A study of Mus musculus with 3 samples.

How the data were processed

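The samples were 3 single-cell libraries of macrophages from the sciatic nerve of C57BL/6 mice, an inbred laboratory strain. 1 library came from uninjured nerve (steady state), 1 from nerve 1 day after nerve crush and 1 from nerve 5 days after nerve crush. Nerve crush is an injury that severs the axons and leaves the outer nerve sheath in place. The labels name the droplet method as 10x Genomics chemistry version 1, and the submitters' processing notes name Cell Ranger 2.0.2 and the mouse build mm10. How the cells were sorted and how many animals went into a library are not given in the sources used here. The microarray and bulk RNA libraries that the series describes were not analysed here.

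The deposited tables hold, per gene and cell barcode, whole-number counts of unique molecular identifiers (UMIs, tags that count each captured RNA molecule once), not normalized. Each sample's table had 27998 genes. The tables held 731, 2796 and 2059 barcodes for steady state, day 1 and day 5, equal to the number of cells the labels state. A deposited table that pools the 3 libraries, with 5586 barcodes that carry a library name as a suffix, held 14774638 UMIs, which is 97.5% of the 15158309 UMIs in the sample tables. No gene had more UMIs there than in the sample tables together, and the pooled table was not used in any comparison. Because free RNA and barcode calling were handled before deposit in steps that are not given in the sources used here, low levels of a gene in a cell can be background.

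Barcodes were kept with at least 200 detected genes and at most 10% mitochondrial UMIs, which removed 6 of 5586. Doublets were called per library with scrublet as run by scanpy 1.11.5, and 18 of 5580 cells (0.323%) were called and left out. So few calls cannot be relied on, and whether doublets were removed before deposit is not given in the sources used here, so doublets remain possible in every result. The cells used were 718 from steady state, 2793 from day 1 and 2051 from day 5. Total UMIs per library were 1658022, 7975791 and 5524496, and the median UMIs per cell were 2235, 2555 and 2470.

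The cells of the 3 libraries were clustered together without integration (Leiden algorithm at resolution 1, 2000 variable genes, 30 principal components, 15 neighbours; python-igraph 0.11.9). The steady-state cells were also clustered by themselves. The genes of 8 lists were left out of the variable genes, so that they could be compared between clusters. Cluster names come from marker lists fixed before the data were examined. The rule that turns markers into a name was set after the clusters had been seen. It gave a cluster the class with the most markers at least 2-fold above the other clusters (offset 10 CPM, where CPM is defined with the comparisons). It asked for at least 3 such markers, at least 2 of them among the 10 leading genes, and no other class with more there. All other clusters keep their number. No cluster met the rule for endoneurial macrophages, the class planned as the partner of epineurial macrophages, so the epineurial-like cells were compared with the other unnamed steady-state cells.

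For comparisons between libraries, UMIs were summed over the monocyte and macrophage cells, that is all kept cells outside the dendritic cell-like cluster: 717, 2771 and 2034 cells. Their sums were expressed as CPM, the UMIs of a gene scaled to a common total of 1e6, and levels of 2 libraries or classes were compared as a ratio of CPM. Each ratio has an exact conditional binomial interval, each CPM an exact Poisson interval and each share of cells an exact Clopper-Pearson interval, all at 95%. These intervals cover counting error only. With 1 library per time point there was no replicate and no test was possible, so each comparison is between libraries and gives no p-value. A count of 0 was replaced by 3 counts per library or class and gives a bound, also for shares of cells. These 3 counts correspond to 1.85, 0.381 and 0.553 CPM in steady state, day 1 and day 5.

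Genes were named by a rule fixed before the data were examined. It took the 6 genes with the largest CPM ratio in each direction among genes with at least 100 CPM in either library, leaving out mitochondrial, ribosomal protein, hemoglobin, immunoglobulin and predicted genes. It also took up to 4 members of each list with the largest ratio among those with at least 50 CPM. The 18 lists were also fixed before the data were examined. For each list, the median log2 ratio over members with at least 10 CPM was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. A list is said to stand apart when its percentile was under 2.5 or over 97.5, as a description of these libraries. The interval of a list median comes from 500 Poisson redraws of its counts. The lists of epineurial, endoneurial, monocyte and cell cycle genes overlap the markers that named the clusters. 7 list or marker genes had no entry under the names used here: Clec7a, Ighm, Igkc, Selenop, Trac, Trbc1 and Trbc2. The values of 2 genes that the rule or the markers take in are not reported here.

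Cycling cells were counted after thinning each cell to 1000 UMIs, leaving out shallower cells. A cell counted as cycling with at least 3 UMIs over the cycling cell markers. The ratio, list and interval steps were tested on simulated counts for all 27998 genes with 200 genes changed. For day 1 over steady state, day 5 over steady state and day 5 over day 1 alike, 100 of 100 genes changed 8-fold and 0 of 100 genes changed 2-fold came out at least 4-fold apart. The simulated counts held Poisson counting noise only, without variation between cells, animals or libraries. They check the computing steps and say nothing on how libraries of the same time would differ. Alternatives tried were other scalings, filters, cell sets, clustering resolutions, marker minimums, and clustering with no list left out. Gene positions were taken from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. The deposited tables pair no gene identifiers with the symbols, so identifiers were matched by symbol. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.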

Results

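Single-cell RNA profiles of sciatic nerve macrophages were compared between uninjured nerve and nerve 1 day and 5 days after crush. Each time point was 1 library, with 718 cells from steady state, 2793 from day 1 and 2051 from day 5 after filtering. The median UMIs per cell were 2235, 2555 and 2470, so depth per cell was similar, and the median genes per cell were 699.5, 891 and 840. There were no replicates. All intervals are at 95% and cover counting error only, and each value describes these libraries.

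Most cells of each library fell into clusters that held few cells of the other libraries. Clusters 1 and 4 held 94.7% of the steady-state cells (interval 92.8 to 96.2), 1.58% of the day 1 cells and 6.29% of the day 5 cells. Clusters 7, 9, 10 and 11 held 86.2% of the day 1 cells (84.9 to 87.5), 4.78% of the day 5 cells, and 0 of 718 steady-state cells, which allows a share of up to 0.418% by 3 counts and of up to 0.512% by the exact interval. Clusters 2 and 3 held 85.6% of the day 5 cells (84.0 to 87.1), 7.02% of the day 1 cells and 3.20% of the steady-state cells. With 1 library per time, a cluster made mostly of 1 library can reflect that library as well as a cell type, so these shares are not read as numbers of cells gained or lost.

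By the marker rule, cluster 1 was epineurial macrophage-like, led by the lectin receptor genes Cd209f, Cd209g and Cd209d with Fcna and Retnla. Epineurial macrophages lie in the outer sheath of the nerve. Clusters 7 and 9 were monocyte-like. Cluster 7 was led by Ly6c2 and by interferon response genes such as Rsad2, and cluster 9 by Dmkn, Lrg1, Chil3 and Vcan. Cluster 5 was cycling cell-like, led by Birc5 and Ube2c, and cluster 6 dendritic cell-like, led by Ccl17 and Ccr7. The other clusters stayed unnamed. Cluster 2 was led by Ccl8, cluster 3 by Gdf15 and Apoe, cluster 4 by Lilra5 and Hpgd, cluster 8 by Stard6, Ch25h and Ccl12, cluster 10 by Pf4 and cluster 11 by Cxcl3 and Slpi. Clusters 2 and 10 held shallow cells, with median UMIs of 1302.5 and 1395 against 3441.5 in cluster 3 and 4161 in cluster 9.

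**Figure D1:**
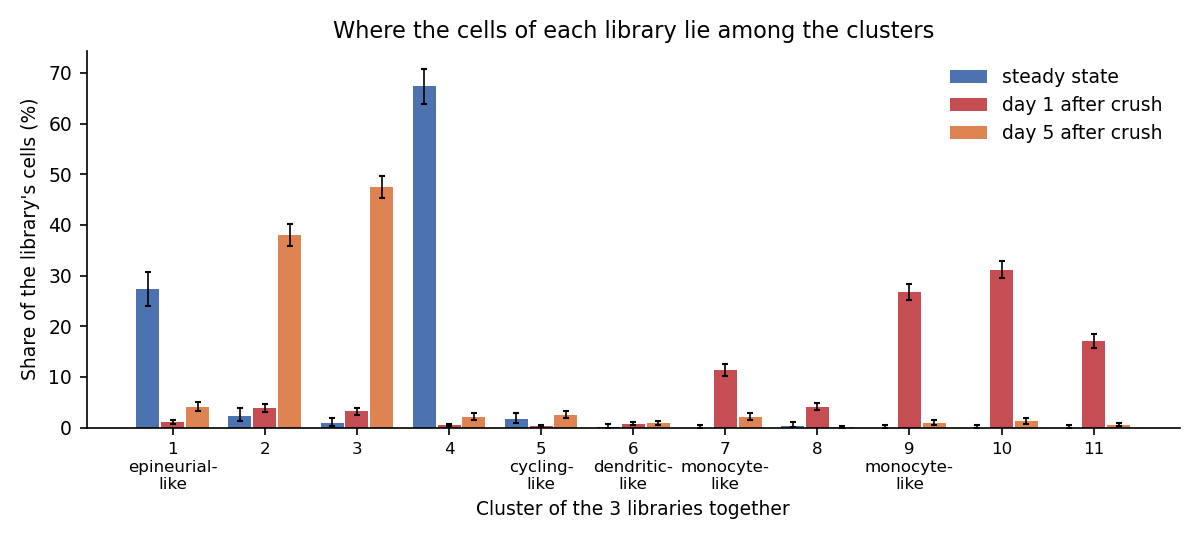
Share of each library's cells (percent, vertical axis) in each of the 11 clusters (horizontal axis), with exact 95% binomial intervals as error bars and 1 colour per library. The steady-state bars are tallest at clusters 1 and 4, the day 1 bars at clusters 9, 10 and 11, and the day 5 bars at clusters 2 and 3.

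The epineurial-like cluster held 27.3% of the steady-state cells (196 of 718, 24.1 to 30.7), 1.11% of the day 1 cells (31 of 2793, 0.755 to 1.57) and 4.14% of the day 5 cells (85 of 2051, 3.32 to 5.10). The monocyte-like clusters held 0 of 718 steady-state cells, 38.1% of the day 1 cells (36.3 to 39.9) and 3.07% of the day 5 cells (2.37 to 3.91). The unnamed clusters 10 and 11, which stood outside that class under a rule set after the data had been seen, held a further 870 and 475 day 1 cells. The day 1 share named monocyte-like was 50.3% at clustering resolution 0.5 and 8.59% with no list left out, so it follows the setting. Dendritic cell-like cells made up 0.139%, 0.788% and 0.829% of the 3 libraries. Markers of other cell types were seen too. Over the monocyte and macrophage cells, the fibroblast gene Dcn was at 17.9, 10.2 and 15.8 CPM for steady state, day 1 and day 5, and the endothelial gene Egfl7 at 22.2, 2.28 and 0.553 CPM. The neutrophil marker Mmp9 was at 114, 36.8 and 9.95 CPM and the B cell marker Cd79b at 46.9, 9.65 and 27.6 CPM. The T cell gene Cd3g had 5 UMIs, all at day 5, and Cd3e 0 UMIs in all 3 libraries. Cluster 4 held 168 UMIs of Dcn, 142 of them in its day 1 and day 5 cells. Of these, 140 lay in 6 cells that the clustering with no list left out put in a fibroblast-like cluster of 9 cells. The neutrophil gene S100a8 had 0 UMIs in steady state, and was at 30.1 CPM at day 1 and 2.03 CPM at day 5.

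The steady-state library was used to compare the epineurial-like cells with the other cells of the uninjured nerve, over genes that had no part in the clustering. The epineurial-like cells had lower list medians for inflammatory, antigen presentation, immediate early and microglia-associated genes. Their list medians for interferon response and complement genes were higher, with complement genes going both ways. Il1b, which encodes interleukin-1 beta, was at 47.8 CPM in the epineurial-like cells (29.2 to 73.8) and 528 CPM in the other cells (488 to 570), a log2 ratio of -3.46 (-4.19 to -2.82). The interferon-induced gene Ifit3 was 10.7-fold higher (6.76 to 17.6), and the complement factor B gene Cfb was 18.8-fold higher (8.85 to 45.7).

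This clustering of steady state alone put 185 of 718 cells (25.8%, 22.6 to 29.1) in the epineurial-like cluster and 533 in 7 unnamed clusters. Among the unnamed was its mixed cluster 2 of 87 cells, led by Ccl17 and Napsa. That cluster had 15 cycling cell markers at least 2-fold above the other clusters. Of the 17 measured inflammatory cytokine and chemokine genes, 14 were at least 2-fold lower and 1 at least 2-fold higher in the epineurial-like cells (median log2 ratio -2.08), with Ccl3 10.7-fold and Cxcl10 11.2-fold lower. All 8 measured genes of class II antigen presentation were at least 2-fold lower (median -1.83), with Cd74, the class II invariant chain, at 9860 against 36186 CPM. Of the 22 immediate early and heat shock genes, 14 were at least 2-fold lower (median -1.14), among them Egr2 (6.72-fold) and Fos (3.51-fold). Of the 12 microglia-associated genes, 6 were at least 2-fold lower and none at least 2-fold higher (median -1.16). St3gal6 was 5.36-fold and Gpr34 2.89-fold lower. Of the 13 interferon response genes, 10 were at least 2-fold higher (median 1.53), including Oasl2 (3.72-fold) and Irf7 (3.37-fold). Of the 12 complement genes, 5 were at least 2-fold higher and 2 lower (median 0.73). C4b was 8.80-fold and Cfp 4.43-fold higher, while the receptor gene C3ar1 was 5.92-fold lower. The percentiles among random lists were 98.9 for complement, 100 for interferon response and at most 0.01 for the 4 lower lists.

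The lipid handling and lysosome list (median 0.15) and the iron and heme list (median 0.66, percentile 97.05) did not stand apart, though Ctsd was 3.42-fold higher and Cd9 13.7-fold lower in the epineurial-like cells. The other cells were not called endoneurial. Cx3cr1 was 16.1-fold and Ccl12 4.90-fold higher in them, but the planned endoneurial marker Mgst1 was 3.94-fold higher in the epineurial-like cells. Unlike the list genes above, these marker genes were not left out of the clustering, so their ratios are not independent of it. A median-of-ratios scaling lowered all log2 ratios of this comparison by 0.11.

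**Figure D2:**
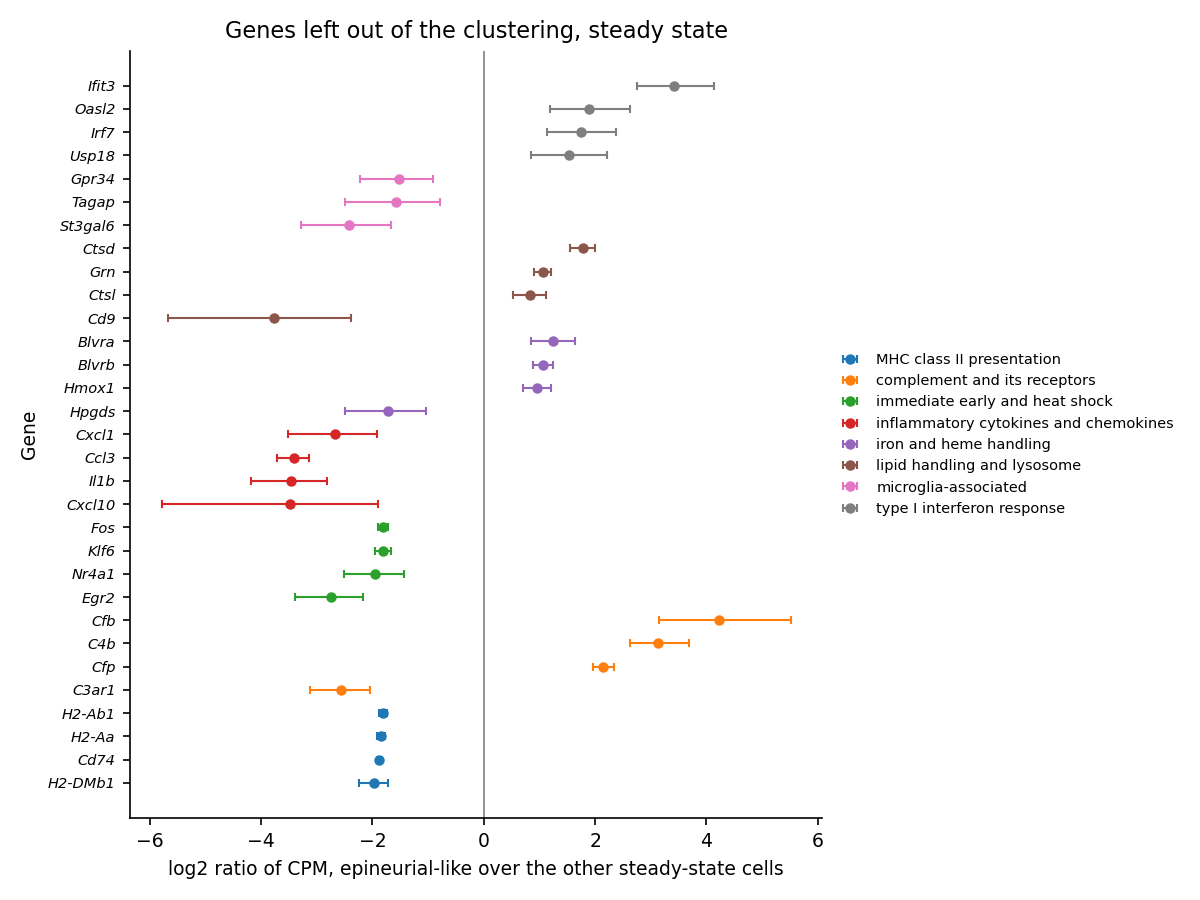
log2 ratio of CPM in epineurial-like over other steady-state cells (horizontal axis) for named genes of the 8 lists left out of the clustering (vertical axis), with exact 95% counting intervals and 1 colour per list. Il1b, Ccl3 and Cxcl10 lie far to the left and Cfb, Ifit3 and C4b far to the right.

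Day 1 was compared with steady state to describe the macrophages found early after crush. Genes of wound repair, glycolysis and monocytes were far higher at day 1, and genes of resident and epineurial macrophages and of antigen presentation were lower. Arg1, the arginase that turns arginine into ornithine, was at 4529 CPM at day 1 and had 1 UMI (0.618 CPM) in steady state, a ratio of 7335 (1316 to 289709). Spp1, which encodes the secreted protein osteopontin, was at 8261 against 14.2 CPM, 582-fold higher (388 to 918). Retnla, a secreted protein gene that marks epineurial macrophages, was at 85.2 against 6786 CPM, 79.7-fold lower (73.7 to 86.3).

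Of 2772 genes with at least 50 CPM in either library, 142 were at least 4-fold higher and 141 at least 4-fold lower at day 1. The other genes with the largest ratios upward were the chemokine gene Cxcl3 (666-fold, 119 to 26302, 1 UMI in steady state), the matrix genes Thbs1 (486-fold, 166 to 2359, 3 UMIs in steady state) and Fn1 (221-fold, 112 to 513), and the protease inhibitor gene Timp1 (263-fold, 47.1 to 10391, 1 UMI in steady state). Downward they were Pla2g2d (189-fold), Lilra5 (170-fold), Gpr34 (116-fold), Sult1a1 (103-fold) and Cd209f (87.3-fold). Of the 23 wound repair and alternative activation genes, 14 were at least 2-fold higher and 1 lower (median log2 ratio 1.91). Of the 21 genes of glycolysis and hypoxia, 19 were at least 2-fold higher (median 2.51), including the lactate transporter gene Slc16a3 (160-fold, 44.2 to 1321, 2 UMIs in steady state), Hif1a (16.7-fold) and Pgk1 (10.1-fold). Of the 16 monocyte and granule genes, 11 were at least 2-fold higher (median 3.04), with Chil3 and Hp both 71.8-fold and Plac8 51.5-fold higher.

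The lipid handling and lysosome genes were higher (14 of 28 at least 2-fold, 3 lower, median 0.98). Fabp5, a fatty acid binding protein gene, was 107-fold higher (70.9 to 171), and Gpnmb, at 137 CPM against 0 UMIs in steady state, was at least 60.2-fold higher by the exact limit (74.2-fold with 3 counts in place of 0). The interferon response genes had a median of 0.75, with 7 of 15 at least 2-fold higher, among them Isg15 (5.22-fold). All 7 measured class II genes were at least 2-fold lower (median -2.93), with Cd74 at 3343 against 29316 CPM. The epineurial macrophage markers were lower (13 of 15 at least 2-fold, median -3.36), as were the resident macrophage core genes (10 of 17, 2 higher, median -1.76), with Cd81 31.4-fold and Timd4 21.3-fold lower. The microglia-associated genes were lower (9 of 12, median -2.54), with St3gal6 25.6-fold lower.

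The complement genes had a median of -0.58, with 5 of 12 at least 2-fold lower and 2 higher. C1qa was at 1574 against 7954 CPM. The 2 higher genes, named after their values were seen, were C3 (46.1 against 2.47 CPM) and Itgam (246 against 51.3 CPM). The immediate early and heat shock genes had a median of -1.86, with 17 of 22 at least 2-fold lower, among them Egr1 (9.52-fold) and Jun (6.73-fold). The cell cycle genes had a median of -2.40, with 13 of 17 at least 2-fold lower and Stmn1 5.28-fold lower. The inflammatory list went both ways: 6 of 19 genes were at least 2-fold higher, such as Osm (8.13-fold), and 4 lower, such as Ccl3 (3.79-fold). Its median of -0.31 and its mean of 0.52 differ in sign. The lists that did not stand apart were iron and heme handling (median 0.16, mean -0.36), oxidative phosphorylation (0.63), endoneurial markers (-0.95), unfolded protein stress (0.34) and scavenger receptors (0.04), although Clec4d of the last list was 108-fold higher. Among the lists that stood apart, the percentiles nearest the middle were 99.025 for interferon response and 1.325 for the inflammatory list.

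**Figure D3:**
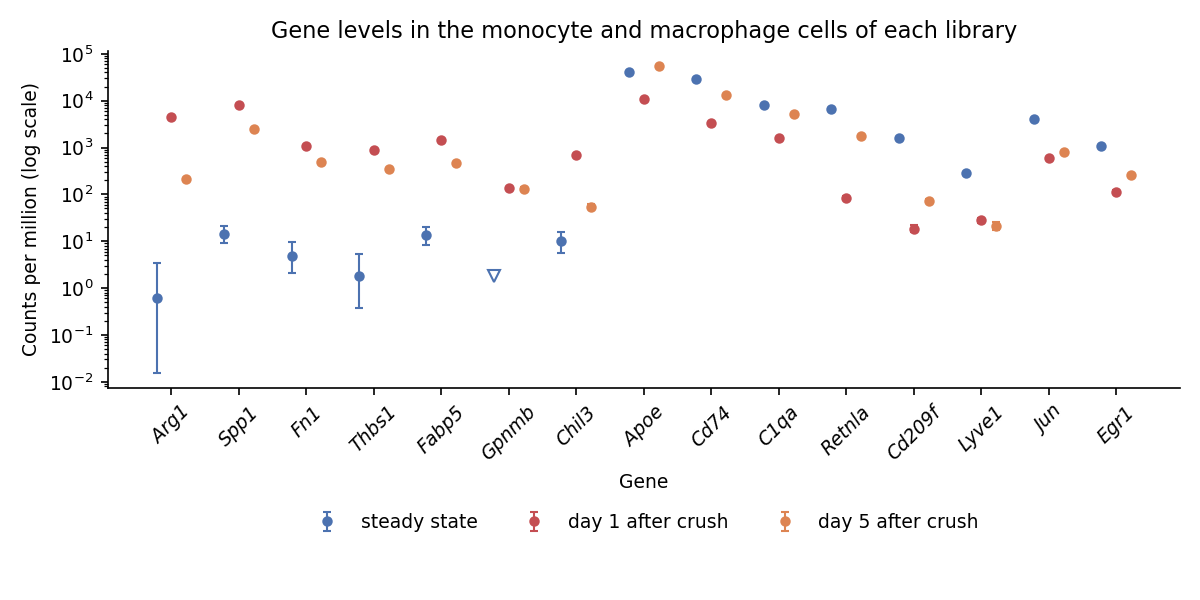
CPM of 15 genes (log scale, vertical axis) in the monocyte and macrophage cells of each library, with exact 95% Poisson intervals; an open triangle stands for 0 UMIs, drawn at the floor of 3 counts. Arg1, Spp1, Fn1, Thbs1 and Chil3 are highest at day 1, and Cd74, Retnla, Cd209f and Jun in steady state.

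Day 5 was compared with steady state to describe the cells found later after crush. The list medians of wound repair, lipid and monocyte genes were still higher than in steady state. Those of epineurial and resident macrophage genes were still lower. Arg1 was at 213 CPM against 0.618 CPM, a ratio of 345 (61.7 to 13619). Spp1 was 171-fold higher (114 to 271) and Fn1 99.9-fold higher (50.6 to 232). Timd4, a phosphatidylserine receptor gene of resident macrophages, was 57.6-fold lower (32.2 to 113), and Cd209f was 22.5-fold lower (20.2 to 25.0).

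Of 2586 genes with at least 50 CPM, 51 were at least 4-fold higher and 70 at least 4-fold lower at day 5. Gpnmb, with 0 UMIs in steady state, was at least 57.6-fold higher by the exact limit (71.0-fold with 3 counts in place of 0), at 132 CPM. The other leading genes upward were Thbs1 (189-fold, 64.7 to 919) and Ly6a (79.1-fold, 27.0 to 385), each with 3 UMIs in steady state. Downward they were Pla2g2d (130-fold), Cd209b (56.5-fold), Cd209g (33.4-fold), Lilra5 (32.7-fold) and Cd209d (30.7-fold). Wound repair genes had a median log2 ratio of 1.44 (13 of 24 at least 2-fold higher, 2 lower), monocyte and granule genes 1.38 (8 of 14 higher), glycolysis and hypoxia 0.81 (8 of 20 higher), lipid handling and lysosome 0.59 (11 of 25 higher, 1 lower) and oxidative phosphorylation 0.49 (2 of 22 higher). Examples were Plac8 (23.9-fold higher), Mif (4.19-fold), Fabp5 (33.7-fold) and Cox7b (2.10-fold).

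Epineurial markers had a median of -2.46 (14 of 15 at least 2-fold lower, 1 higher), with Mgl2 14.5-fold lower. Immediate early and heat shock genes had a median of -1.82 (16 of 22 lower), with Ier2 6.62-fold and Klf2 5.74-fold lower. Microglia-associated genes had a median of -1.33 (7 of 13 lower, 3 higher), with Siglech 48.1-fold and St3gal6 10.9-fold lower. Resident core genes had a median of -0.76 (7 of 17 lower), with Lyve1 13.2-fold lower. The class II genes had a median of -0.64 with 1 of 8 at least 2-fold lower, Cd74 at 13512 against 29316 CPM. Inflammatory genes had a median of -0.49 (8 of 18 lower, 6 higher), with Ccl2 4.25-fold lower and Osm 4.38-fold higher, and complement genes -0.38 (2 of 12 lower, 2 higher). Interferon response (median 0.36), iron and heme handling (0.17, mean -0.25), cell cycle (-0.04), endoneurial markers (0.36, mean -0.26), unfolded protein stress (0.04, mean -0.12) and scavenger receptors (0.22) did not stand apart. Among the lists that did, the percentiles nearest the middle were 98.78 for oxidative phosphorylation and 1.96 for complement.

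**Figure D4:**
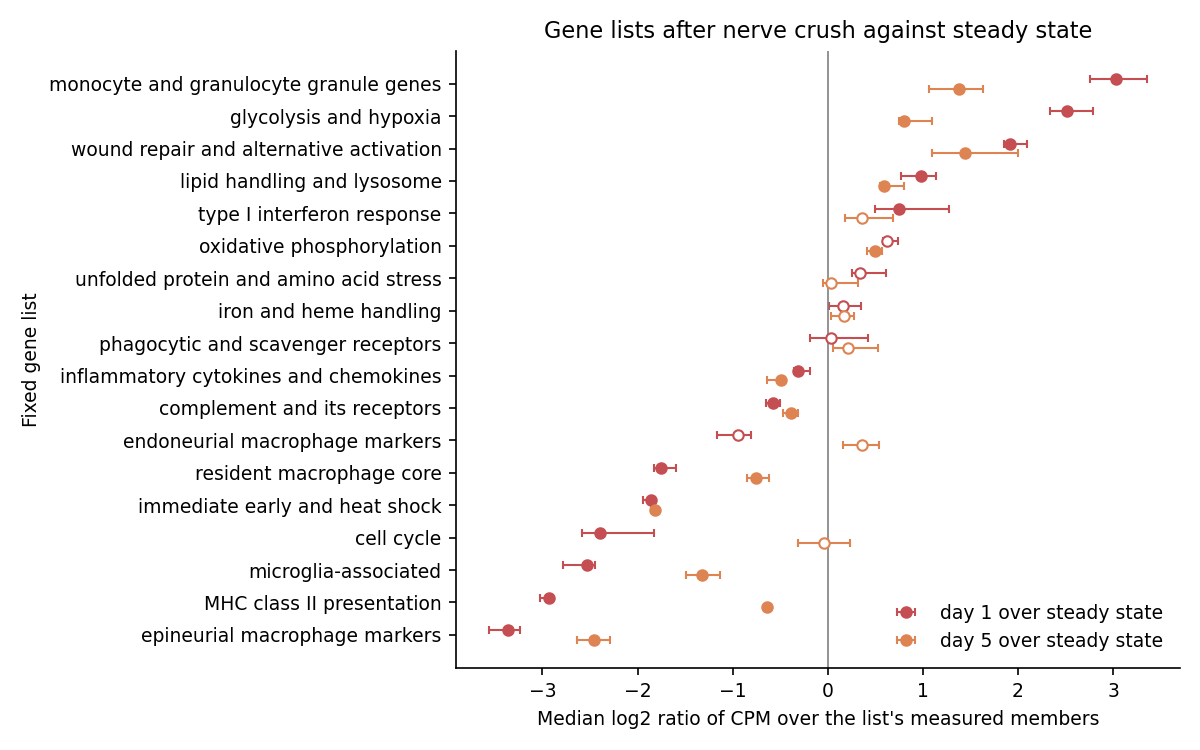
Median log2 ratio of CPM (horizontal axis) of 18 gene lists (vertical axis) for day 1 and day 5 over steady state. Filled points stood apart from random lists, open points did not, and bars are 95% counting intervals; glycolysis and hypoxia had medians of 2.51 at day 1 and 0.81 at day 5.

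Day 5 was compared with day 1 to set the later against the earlier injured nerve. The list medians of antigen presentation, complement and epineurial marker genes were higher at day 5. Those of wound repair, glycolysis and monocyte genes were lower. Among the complement genes, 4 of 12 were at least 2-fold higher and 1 lower. Retnla was at 1805 CPM at day 5 and 85.2 CPM at day 1, 21.2-fold higher (19.6 to 23.0). The day 5 cells had 9801 UMIs of it. Over the 3 libraries together, the unnamed clusters 2 and 3, which held most day 5 cells, had 3190 and 3761 UMIs of Retnla. Its rise is therefore not read as a return of epineurial macrophages. Apoe, a lipid transport protein gene, was at 54595 against 10922 CPM, 5.00-fold higher (4.96 to 5.04). Arg1 was 21.3-fold lower (20.1 to 22.6), and Ppbp, which encodes the chemokine platelet basic protein, was 249-fold lower (142 to 481).

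Of 2548 genes with at least 50 CPM, 24 were at least 4-fold higher and 29 at least 4-fold lower at day 5. Upward the next genes were Pltp (8.73-fold), Ramp1 (7.16-fold), Tmem176b (6.42-fold), Tmem176a (5.76-fold) and Cx3cr1, the fractalkine receptor gene (5.37-fold). Downward they were Cxcl3 (106-fold), Slpi (28.1-fold), Ifitm1 (15.7-fold) and Chil3 (12.9-fold). All 8 class II genes were at least 2-fold higher (median log2 ratio 2.16), with Cd74 4.04-fold and H2-Eb1 5.32-fold higher. Cell cycle genes had a median of 1.84 (11 of 15 higher) with Stmn1 3.80-fold higher, and microglia-associated genes 1.24 (8 of 11 higher) with Fcrls 3.49-fold higher. Epineurial markers had a median of 1.00 (8 of 15 higher) and endoneurial markers also 1.00 (2 of 5 higher). Complement genes had a median of 0.37 (4 of 12 higher, 1 lower), with C1qa 3.35-fold higher, and immediate early genes 0.15 (1 of 21 higher).

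Glycolysis and hypoxia genes had a median of -1.42, with 19 of 21 at least 2-fold lower and Pgk1 11.7-fold lower. Wound repair genes had a median of -1.24 (14 of 25 lower, 3 higher), with Timp1 11.8-fold lower. Monocyte and granule genes had a median of -1.23 (10 of 16 lower, 1 higher), with Vcan 39.1-fold lower. Inflammatory genes had a median of -0.59 (4 of 19 lower), with Ccl7 2.41-fold lower, and interferon genes -0.49 (3 of 16 lower, 1 higher). The lipid handling list did not stand apart (median 0.02, mean -0.25): Apoe was higher, while Fabp5 was 3.19-fold and Lgals3 2.31-fold lower. Iron and heme handling (-0.11, mean 0.25), resident core (0.12), oxidative phosphorylation (-0.30), unfolded protein stress (-0.41) and scavenger receptors (0.09, mean -0.27) also did not stand apart. Among the lists that did, the percentiles nearest the middle were 98.125 for immediate early genes and 0.33 for interferon response.

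The same classes were then compared between libraries. In epineurial-like cells, day 5 (85 cells) was lower than steady state (196 cells) in immediate early and heat shock genes (median log2 ratio -1.05, 12 of 22 at least 2-fold lower, 1 higher), with Ier2 3.38-fold and Dusp1 2.81-fold lower. Their markers were mostly lower too, with Cd209g 4.27-fold, Cd209f 2.74-fold and Folr2 2.16-fold lower, Retnla 1.15-fold lower (1.10 to 1.20) and Ccl8 3.34-fold higher. These marker genes took part in the clustering, so their values within the class are not independent of it. Wound repair genes were higher (10 of 21 at least 2-fold, 1 lower, median 0.88). Fn1 was at 235 CPM (36 UMIs) against 4.74 CPM (2 UMIs), a ratio of 49.6 (12.8 to 425). Spp1 had a ratio of 22.0 (7.81 to 85.7, 32 and 4 UMIs). Over all monocyte and macrophage cells of day 5, Fn1 was at 493 CPM and Spp1 at 2436 CPM, so background RNA from other day 5 cells is not excluded for these counts. Cell cycle genes (median 1.05, 9 of 15 at least 2-fold higher) and monocyte genes (0.91, 4 of 10) were higher. Epineurial markers (-0.78, 5 of 15 at least 2-fold lower, 1 higher) and resident core genes (-0.40, 4 of 17 lower, 2 higher) had lower medians. The class held 64 day 5 cells at resolution 0.5, 61 with no list left out and 87 at resolution 2. Day 5 cells that other settings place in other clusters are therefore not excluded as a source of these differences. None of the other 7 lists left out of the clustering stood apart, such as class II genes at 0.52, with H2-Aa 1.53-fold higher. The median depth was 1538 UMIs at day 5 and 2200.5 in steady state, and a median-of-ratios scaling lowered all log2 ratios by 0.14.

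In monocyte-like cells, day 5 (63 cells, 44 of them in cluster 7) was set against day 1 (1063 cells, 746 of them in cluster 9), so different clusters held most of the class. Class II genes were higher at day 5 (7 of 7 at least 2-fold, median 2.20), with H2-Aa 6.19-fold higher (5.89 to 6.49). Interferon genes were higher (7 of 17, median 0.69), with Ifit2 9.43-fold higher (5.81 to 15.1). Cluster 7, led in part by interferon response genes, held 44 of the 63 day 5 cells but 317 of the 1063 day 1 cells. A different mix of clusters 7 and 9 is therefore not excluded as the source of the interferon difference. The same holds for the class II, microglia-associated, endoneurial, wound repair and glycolysis differences of this class, which are not read as changes within monocytes. Microglia-associated genes (0.76, -0.02 to 1.26, 4 of 9 at least 2-fold higher) and endoneurial markers (0.94, 2 of 5 higher, 1 lower) also stood apart upward. Wound repair genes (-0.89, 10 of 22 at least 2-fold lower, 4 higher) and glycolysis genes (-0.74, 5 of 21 lower, 1 higher) were lower. Cxcl3, with 0 UMIs at day 5, was at least 15.8-fold lower by the exact limit (19.5-fold with 3 counts in place of 0).

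In cluster 3, microglia-associated genes were higher at day 5 (975 cells) than at day 1 (89 cells), with 6 of 11 at least 2-fold higher (median 1.15). Fcrls was 5.15-fold (3.32 to 8.46) and Trem2 2.38-fold higher. Class II genes had a median of 0.04 there, and H2-Aa was at 7546 against 6872 CPM. Monocyte and granule genes were lower at day 5 (-0.77, 7 of 15 at least 2-fold lower, percentile 0.035), as were wound repair (-0.53, 9 of 23 lower, 2 higher) and glycolysis genes (-0.49, 4 of 20 lower). The median depth was 3493 UMIs at day 5 and 2693 at day 1. In cluster 2 (780 and 107 cells), class II genes had a median of 0.92, with 3 of 8 at least 2-fold higher and H2-Eb1 2.91-fold higher. The microglia-associated genes did not stand apart there (0.16, 5 of 13 higher, 2 lower, percentile 88.29). Lower there were monocyte and granule genes (-1.05, 8 of 16 at least 2-fold lower, 1 higher, percentile 0), wound repair (-0.75, 7 of 23 lower, 1 higher) and glycolysis genes (-0.66, 5 of 20 lower, 2 higher). These lower lists took part in the clustering, unlike the microglia-associated and class II lists. A median-of-ratios scaling subtracted a shift of -0.17 in cluster 3 and of -0.29 in cluster 2 from the log2 ratios. It therefore raised all of them and made the lower medians smaller drops.

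Cycling cells, with at least 3 UMIs of cell cycle markers after thinning to 1000 UMIs, made up 1.11% of the steady-state cells (7 of 628, 0.449 to 2.28), 0.280% of the day 1 cells (7 of 2496, 0.113 to 0.577) and 1.98% of the day 5 cells (35 of 1769, 1.38 to 2.74). Thinning left out 90, 297 and 282 shallower cells. Without thinning the shares were 2.37%, 0.609% and 3.07%. The intervals of day 1 and day 5 do not overlap, while those of steady state and day 5 do.

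The main genes named lie in mm10 as follows, each annotated as protein coding. Arg1 (ENSMUSG00000019987.9) spans chromosome 10 from 24915221 to 24927484, and Spp1 (ENSMUSG00000029304.14) chromosome 5 from 104435118 to 104441050. Retnla (ENSMUSG00000061100.4) spans chromosome 16 from 48842551 to 48844461, and Cd209f (ENSMUSG00000051906.15) chromosome 8 from 4102787 to 4105835. Cd74 (ENSMUSG00000024610.15) spans chromosome 18 from 60803848 to 60812652, and Gpnmb (ENSMUSG00000029816.10) chromosome 6 from 49036546 to 49070929. Ppbp (ENSMUSG00000029372.7) spans chromosome 5 from 90768518 to 90770063, and Cx3cr1 (ENSMUSG00000052336.7) chromosome 9 from 119901616 to 120069879.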

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

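The runs with all barcodes for class shares, without the mixed steady-state cluster 2 and without fibroblast-like cells were chosen after seeing the data. No called direction turned under any alternative run: of 1931 values of single genes, lists and depths, 1723 stayed within their counting interval and 208 moved outside it, and 142 of 169 main results were the same. No paired analysis was possible because each time point has 1 library. With no low-level filter beyond 3 counts, the genes at least 4-fold higher and lower numbered 569 and 1261 for day 1 over steady state, 390 and 630 for day 5 over steady state, and 465 and 262 for day 5 over day 1. That filter admits genes of few counts, whose ratios are imprecise. Class shares followed the clustering. The monocyte-like share at day 1 was 50.3% at resolution 0.5, 18.0% at resolution 2, 8.59% with no list left out, 12.3% with doublets kept and 12.1% with all barcodes. At day 5 it was 2.15% at resolution 2, 0.341% with no list left out, 2.14% with doublets kept and 1.85% with all barcodes. With doublets kept and with all barcodes, 1033 and 906 day 1 cells fell in clusters named Arg1-expressing macrophage-like. With all barcodes, 909 cells, 790 of them from day 5, were named erythroid cell-like, and all 12010 hemoglobin UMIs of that cluster lay in 3 barcodes that the filter removes. The dendritic cell-like share at day 1 was 1.22% at resolution 2, 2.47% with no list left out and 0.394% with doublets kept. With doublets kept it was 0% in steady state and 0.291% at day 5. The epineurial-like share at day 5 was 3.12% at resolution 0.5 and 2.97% with no list left out. The cycling cell-like share at day 1 was 4.12% at resolution 0.5. Cycling cells not thinned made up 2.37%, 0.609% and 3.07% for steady state, day 1 and day 5. With thinning to 1000 UMIs, 1.13% of the day 5 cells had at least 5 UMIs. The cause was not tested for these shares. Without the mixed cluster 2, 2 lists stood apart upward and 4 downward in steady state. Depth limits genes under 50 CPM in steady state, the smallest library.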

Other observations

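Of the tests here, those on the mix of cells and on the microglia-associated genes of cluster 8 were set before their result was seen, and the others after it. Cluster 8 held 115 of the 2793 day 1 cells (4.12%, 3.41 to 4.92), 2 steady-state cells and 1 day 5 cell. Ccl12, a monocyte-attracting chemokine gene, was at 5301 CPM in its day 1 cells against 512 CPM in the day 1 cells of clusters 7, 9, 10 and 11. The day 1 cells of those clusters are called recruited below as a label only, since their origin was not tested. The mannose receptor gene Mrc1 was at 1200 against 227 CPM, and the lectin gene Mgl2 at 977 against 9.08 CPM. Lyve1 was at 332 against 8.65 CPM and Cd81 at 753 against 20.3 CPM. Retnla was at 61.8 CPM, far from the 22089 CPM of the epineurial-like cells in steady state. The genes of cluster 8 named here were chosen after their values were seen.

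Cluster 8 may hold steady-state cells that remained in the nerve at day 1, a hypothesis that the microglia-associated list left open: its median log2 ratio over clusters 7, 9, 10 and 11 was 0.91 (-0.01 to 1.45, 10 genes), between the bounds of 0 and 1 set for it. Doublets of a steady-state and a recruited cell would carry the genes of both. Recruited cells with free RNA of steady-state cells would keep their own genes. Over the 12 genes high in the recruited cells and low in steady state, however, cluster 8 had a median of 9.34% of their pooled level. Against the lowest of clusters 7, 9, 10 and 11 the median was 16.2% (quartiles 11.4 and 26.7), with Ppbp highest at 154%. Most of these genes could take part in the clustering, so it was repeated without them and without 31 steady-state genes: 67 of the 115 day 1 cells stayed in a cluster of 73. There the 12 genes had a median of 11.2% of the level in the recruited clusters (quartiles 9.21 and 14.8) and of 14.5% of the lowest of these (11.2 and 20.6). For this cluster, these levels argue against doublets with, or free RNA in, recruited cells that have the usual levels of the 12 genes. Other genes of the recruited cells still took part in the repeated clustering. It can therefore have gathered cells low in the 12 genes, and recruited cells with low levels of them are not excluded. For the other 48 cells neither doublets nor free RNA can be told apart from expression, as the tested genes could help to form cluster 8. The 31 genes, chosen for low levels in the recruited cells, were a median of 4.80-fold above those cells in cluster 8. In the repeated cluster they were a median of 3.25-fold above the recruited clusters, close to the bound of 3-fold set for free RNA. Earlier versions, on Arg1, Spp1 and Mgl2 alone and then on gene sets in the first clusters, had argued against doublets, and on free RNA they had gone from against it to open, with 11 of the 31 genes under a bound of 3-fold, and back.

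Immediate early and heat shock genes were higher in the steady-state library than at either time after crush, with medians of -1.86 at day 1 and -1.82 at day 5. A different mix of clusters could account for part of this but not all. Within cluster 4, formed without these genes, the list was still lower at day 5 (44 cells) than in steady state (484 cells). The list median there was -0.63 (-0.80 to -0.58) with 18 of 22 genes lower, or -0.69 without its 3 fibroblast-like day 5 cells. The kinds of cells inside cluster 4 can also differ between the libraries, so a different mix of cells within it is not excluded. A handling or dissociation difference between the libraries would lower the list in every class, and both clusters compared showed this, the smaller drop being that same -0.63 in cluster 4, with under 50 day 5 cells, and the other, in cluster 1, -1.05 (-1.15 to -0.81). A changed state of the same cells after crush would give the same value of -1.05 in cluster 1. It cannot be told apart from handling, because each time point is 1 library.

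Ppbp was at 20.4 CPM in steady state, 549 CPM at day 1 and 2.21 CPM at day 5. Platelets or their RNA would bring other platelet genes, but Gp9, Itga2b, Gp1bb, Treml1 and Clec1b together had 0 UMIs at day 1 against 4330 of Ppbp, which allows up to 0.0693% of its count. The platelet gene Pf4 was abundant, at 8520 CPM at day 1, but was not counted because it was at 5076 CPM in steady state too, where Ppbp was low. Among the day 1 clusters, Pf4 was highest in cluster 10 (15992 CPM, Ppbp 742 CPM) and next in cluster 11 (8871 CPM). Cluster 2, however, had 8473 CPM of Pf4 with 66.3 CPM of Ppbp. Free Ppbp RNA would lie evenly over the day 1 cells, but its level differed 18.8-fold between the day 1 clusters with at least 50 cells, from 54.0 CPM in cluster 3 to 1014 CPM in cluster 11, and 22.6-fold with Ppbp left out of the clustering. Expression of Ppbp by the macrophages of day 1 stays as a hypothesis, since it was found and tested on the same data, from 1 library of day 1.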
